A study of Saccharomyces cerevisiae and Saccharomyces cerevisiae S288C with 30 samples.

How the data were processed

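Introns and branch points of *Saccharomyces cerevisiae* were measured in 3 kinds of library, 30 libraries in all. RNA-seq covered 26 libraries in 13 groups, with 2 biological replicates in each group. Of these, 6 came from the TruSeq kit (WT, dbr1_null and upf1_null, grown in YPD to OD600 0.5 to 1, RNA quality number at least 8.8, one HiSeq2000 lane). The other 20 came from the Ribo-Zero Gold kit (dbr1, sk1, +rap, -rap, and SK1 cells after 0, 3, 6, 7.5, 8.5 and 12 h in sporulation medium, one NextSeq lane). RNA was extracted with hot acid phenol in both. The groups dbr1, +rap and -rap were S288c, and sk1 and the time course were SK1. Branch-seq, with 3 barcoded gel fractions of a single experiment, and Lariat-seq, with 1 library, both started from lariat RNA isolated on a 2D gel from cells at OD600 0.94 to 0.98. For Branch-seq the lariats were opened with DBR1, tailed with poly(A), reverse transcribed, circularised and sequenced from both ends.

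Per the labels, the authors aligned Branch-seq with Bowtie 1.0.0 and SAMtools 0.1.7a to sacCer2, Lariat-seq with Bowtie 1.0.0 to sacCer3, TruSeq RNA-seq with TopHat2 2.0.0, Bowtie, Cufflinks 2.2.1 and Cuffdiff to sacCer3, and Ribo-Zero RNA-seq with TopHat2 and Bowtie, versions not given, to sacCer3. The deposited Branch-seq values are CPM, scaled read counts, in 1 column for the pooled fractions, at 198 annotated and 268 unannotated branch points. The deposited Lariat-seq values are counts of junction reads at 58 sites. The deposited RNA-seq values are PSI, a fraction from 0.01 to 1 with 2 decimals, for 405 events: 279 annotated introns, 98 unannotated introns, 21 alternative 3′ splice sites (A3SS) and 7 alternative 5′ splice sites (A5SS). The sources used here do not define PSI. From its values it reads as the share of transcripts that retain the intron, and a higher PSI is written below as higher retention. For A3SS and A5SS events the direction of PSI is not given, so their values are reported as they stand. The read counts behind PSI are not given in the sources used here, so the depth per intron is unknown and no counting intervals are given for it. The number of PSI values per library ranged from 384 to 394 in TruSeq and from 231 to 374 in Ribo-Zero libraries.

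Locus tags were matched to gene symbols for all 343 gene identifiers in the PSI table, and 12 events carried no gene. PSI and Lariat-seq coordinates are given on sacCer3 and Branch-seq coordinates on sacCer2. Branch-seq sites were therefore matched to the other assays by gene name only.

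PSI was taken to log2((PSI + 0.01)/(1 − PSI + 0.01)), called log2 odds below. A linear model with a mean for each group was fitted over all libraries of a preparation with limma 3.58.1 in R 4.3.3. Each comparison tested the introns with both values present in both groups, two-sided, with limma's moderated test and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The time course was also tested with limma's F-test over all 6 times. The Ribo-Zero dbr1 and sk1 groups have no control of their own in the labels. They were set against -rap, so that genotype or strain cannot be told apart from other differences between the cultures. The label +rap is used as given. The deposited PSI does not measure expression of DBR1 or UPF1.

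Gene lists fixed before the data were examined were ribosomal protein genes (115 events, 91 of them annotated introns), Meiotic genes (13 genes, 15 introns), Mer1 targets (4 genes, 5 introns), introns known to be regulated or linked to nonsense-mediated decay (15 genes, 19 introns), snoRNA host introns (8 genes, 12 introns), U3 snoRNA genes (2 genes, no event in the PSI table), cytoskeleton (11 genes), RNA processing (11 genes) and mitochondria (6 genes, 4 introns), beside all annotated and all unannotated introns. Each gene list took in every event of its genes, with unannotated introns and A3SS or A5SS events where present. The snoRNA host introns are thus events of host genes, not only the introns that hold a snoRNA. The lists overlap: Mer1 targets are all Meiotic genes, and ribosomal protein genes also appear among regulated and snoRNA host introns. Lists were tested with limma's camera as cameraPR on the normal scores of the moderated statistic, with a preset correlation of 0.01, adjusted over the lists of each comparison. This test asks whether a list moved relative to all other introns, not whether it moved at all. Annotated and unannotated introns make up most events, and unannotated introns lie near the ceiling of PSI, so their shifts are not separate results. A list under 3 measured introns was described but not tested. The lists had first been ranked on the moderated statistic itself. That was changed to normal scores, which camera itself uses, after those results had been seen, and the first version stands among the alternatives. The correlation was also estimated from the data, and fry was run on introns with no missing value.

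For each PSI comparison the genes named are those with the 10 largest rises and the 10 largest falls in mean PSI past the threshold with replicates of the groups apart, up to 4 members of each list, and the introns of Mer1 targets, DBR1, UPF1, ACT1 and SUS1 where measured. For the time course they are the 10 smallest F-test p values and the Meiotic list. For Branch-seq and Lariat-seq they are the 10 highest sites of each set, and unannotated sites seen in both. Some genes among these are not reported here. Tallies of named introns with a library left out cover the largest rises and falls and the genes named in every comparison, not those named as list members alone. The tests, lists, naming rule and most alternatives were chosen before the data were examined. Added afterwards were 12 h against 3 h, the difference in dbr1 effect between preparations, the overlap of +rap and 3 h introns, and Branch-seq signal against intron length and gene class.

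Branch-seq sets were compared by the difference in median log2(CPM + 1) with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Correlations used Pearson's r and Spearman's rho across genes with permutation p. Lariat-seq shares carry exact Clopper-Pearson 95% intervals, which hold counting error alone. These steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with matplotlib 3.10.9 for figures.

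The tests were tested on simulated data built from the replicates' own spread. In the TruSeq design, changes of 1, 2 and 4 log2 odds were found in 35%, 55% and 85% of 20 introns each, and 5 of 317 unchanged introns were called. In the +rap design the shares were 10%, 65% and 100%, and 1 of 246 was called. In the TruSeq design the 5 false calls stood beside 7, 11 and 17 changes found. False calls were thus a larger share of all calls there than the threshold of 0.05 is meant to allow. The dbr1_null and upf1_null calls come from that design, and a single simulated set does not fix the rate. Changes were planted only in introns away from the floor and ceiling of PSI, in the direction of its middle. The shares found therefore do not cover introns near either end. Alternatives were offsets of 0.05 and 0.001, untransformed PSI, introns present in every library, mean PSI between 0.02 and 0.98, the compared groups alone, robust variance moderation, a difference of at least 0.1, a block by replicate number, and leaving out each library. Those added after seeing the data were rDNA events left out, values spread within their rounding, the 7.5 and 8.5 h libraries left out, lists of annotated introns alone and the first ranking of lists.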

Results

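Intron retention was measured as PSI in 26 RNA-seq libraries of budding yeast, 2 replicates in each of 13 groups, beside 3 Branch-seq gel fractions pooled in 1 experiment and 1 Lariat-seq library. The table held 405 events, and between 231 and 394 of them had a value in a given library. Median differences between the replicates of a group were small, 0.02 in TruSeq WT, 0.01 in Ribo-Zero dbr1 and at most 0.04, in the +rap and 3 h groups. All values with ± are the mean and SD of n = 2 libraries, and coordinates of RNA-seq and Lariat-seq are on sacCer3.

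Whether loss of the debranching enzyme Dbr1 changes intron retention was first asked in the TruSeq libraries, dbr1_null against WT. RPL26B, which encodes a protein of the large ribosomal subunit, moved from near the floor to near the ceiling of PSI (chromosome VII, 555831 to 556307, 0.99 ± 0 against 0.06 ± 0.0141; difference 9.42 log2 odds, SE 0.18, adjusted p = 0.00114). Whether this is retained pre-mRNA stays open, as set out under Other observations. RPL40B, a ubiquitin fusion gene, rose from 0.365 ± 0.00707 to 0.715 ± 0.0212 (XI, 618375 to 618742, adjusted p = 0.00608). RPS30A rose from 0.08 ± 0 to 0.22 ± 0.0283 (XII, 712726 to 713155, adjusted p = 0.0262). RPL13A, RPS23A, RPS30B, RPS14A, RPL31B and RPL19B rose by 0.06 or less. The lone fall was at YLL067C, a subtelomeric gene, by 0.01, which is a single step of the 2 decimals given (0.98 ± 0 against 0.99 ± 0, adjusted p = 0.003). Of 377 introns tested, 9 rose and 1 fell, all of them annotated. Introns of SUS1, whose product serves mRNA export, were not past the threshold (the first 0.835 ± 0.177 against 0.85 ± 0.0566, adjusted p = 1; the second 0.54 ± 0.0283 against 0.485 ± 0.0354, adjusted p = 0.374), nor was actin, ACT1 (0.06 ± 0.0283 against 0.03 ± 0.0141, adjusted p = 0.422), or REC107, a Mer1 target (0.99 ± 0 against 0.955 ± 0.0495, adjusted p = 0.546).

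By group, ribosomal protein events supplied all 9 rises in dbr1_null, out of 115 measured (18 rose adjusted over the list alone). Relative to other introns they were shifted upward (camera adjusted p = 1.06e-08, adjusted p = 0.204 with an estimated correlation, and 8.28e-11 to 0.204 over all alternatives). Annotated introns as a class were also shifted up (median PSI 0.307 against 0.212 in WT, adjusted p = 6.37e-06, and adjusted p = 0.012 with an estimated correlation, 1.52e-06 to 0.0459 over all alternatives). The median difference of single annotated introns was 0.035. Among 94 unannotated introns none passed limma's test, and 12 had an unadjusted p under 0.05. Their median PSI in WT was 0.98, close to the ceiling, and together with annotated introns they make up most events, so their place below the other introns in camera is largely the counterpart of the annotated shift. Their median difference was 0 and their mean difference 0.00644 (camera adjusted p = 4.79e-05, adjusted p = 0.00157 with an estimated correlation, 6.09e-06 to 0.0632 over all alternatives, the highest when ranked by the moderated statistic). Regulated introns (17), snoRNA host introns (12), cytoskeleton (11), RNA processing (11), Meiotic (5) and mitochondria (4) introns were not past in limma or camera. RPS9A, with 0.755 ± 0.346 against 0.27 ± 0.212, shows how far replicates of single introns could part. RPL26B passed whichever library was left out (highest adjusted p 0.0161). So did RPS14A, RPL31B, RPL19B and YLL067C, but their replicates were identical to 2 decimals, so leaving one out could not move them. With values spread within their rounding RPL26B and RPL40B passed in all 20 draws and the other 8 calls in none. RPL40B, RPS30A, RPL13A, RPS30B and RPS23A each failed without WT replicate 1 and without WT replicate 2, RPS30B also without dbr1_null replicate 2 and RPS23A without either dbr1_null replicate (up to 0.152). Without dbr1_null replicate 1 the count was 26.

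The upf1_null libraries address which spliced or unspliced transcripts depend on Upf1, a helicase of nonsense-mediated mRNA decay. The ribosomal protein gene RPL28, from the list of introns regulated or linked to nonsense-mediated decay, showed the largest rise (VII, 311016 to 311526, 0.715 ± 0.0636 against 0.15 ± 0.0566, adjusted p = 0.0292), followed by RPL22A (XII, 263206 to 263594, 0.51 ± 0.099 against 0.115 ± 0.00707, adjusted p = 0.0272). HRB1, which encodes a poly(A) RNA binding protein, rose from 0.2 ± 0.0141 to 0.585 ± 0.0636, and RPS13 from 0.14 ± 0.0566 to 0.48 ± 0.0283. BUD25 had tight replicates (V, 184170 to 184677, 0.97 ± 0 against 0.685 ± 0.0212, adjusted p = 0.00148). CIN2, a tubulin folding factor, rose by 0.31, the proteasome subunit gene PRE3 by 0.205, IAI11 by 0.205, TAF14 by 0.2 and RPL36A by 0.185. Each of the 4 falls was by 0.01, a single step of the table: unannotated introns in LSM2, NPL3 and YMC1 (adjusted p = 0.000407 each) and a TAN1 A3SS event (adjusted p = 0.00148). In all, 45 of 382 events rose and 4 fell, with 38 of the rises among 260 annotated introns (medians 0.278 against 0.212). The median difference of single annotated introns was 0.04.

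Of 115 ribosomal protein events 26 rose in upf1_null, 22 of them annotated introns, and none fell (30 and 0 adjusted over the list alone). Their upward shift had camera adjusted p = 1.06e-06 (adjusted p = 0.258 with an estimated correlation, 4.97e-08 to 0.258 over all alternatives). Annotated introns were shifted up (adjusted p = 0.00023, adjusted p = 0.0362 with an estimated correlation, 5.39e-05 to 0.0362 over all alternatives). Unannotated introns, with 6 rises and 3 falls among 95, a median difference of 0 and a mean of 0.0188, lay below the others in camera (adjusted p = 0.00753, adjusted p = 0.0362 with an estimated correlation, 0.000877 to 0.0692 over all alternatives). That call was lost without WT replicate 2 (0.0692) or upf1_null replicate 2 (0.0662), and when ranked by the moderated statistic (0.0653). Of 17 regulated introns RPL28, RPL22A and 1 more rose, the meiotic phospholipase gene SPO1 rose among 5 Meiotic introns (0.98 ± 0 against 0.935 ± 0.00707, adjusted p = 0.0394), and an unannotated RPS22B intron rose among 12 events of snoRNA host genes (0.465 ± 0.0212 against 0.295 ± 0.0354, adjusted p = 0.0475). These lists, cytoskeleton, RNA processing and mitochondria were not past in camera, although the Meiotic list passed without WT replicate 2 (adjusted p = 0.00662, 0.00662 to 0.975 over all alternatives) and RNA processing, with 1 fall among 11, with an estimated correlation (adjusted p = 0.00139, 0.00139 to 0.5 over all). The second SUS1 intron was lower without passing (II, 462430 to 462499, 0.335 ± 0.0212 against 0.485 ± 0.0354, adjusted p = 0.0521), and ACT1 stayed near 0.03 (0.035 ± 0.00707, adjusted p = 0.86). The count rested on each library, with 23 without WT replicate 1, 21 without WT replicate 2, 19 without upf1_null replicate 1 and 16 without upf1_null replicate 2. BUD25 passed whichever was left out (highest adjusted p 0.0285). The 4 falls did too, but with identical replicates that could not move, and with values spread within their rounding they passed in 0 to 2 of 20 draws. Of all 49 calls 6 passed in every draw, BUD25 and RPL28 among them, and 27 in none. The other 9 introns named among the largest rises each failed without at least 2 of these 4 libraries (up to 0.218).

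In the Ribo-Zero libraries, S288c dbr1 cells had far higher intron PSI than the -rap cells used as control. RPS14A, for an abundant protein of the small subunit, stood at 1 ± 0 against 0.035 ± 0.00707 (III, 177907 to 178213, adjusted p = 8.8e-08). RPS21B was at 1 ± 0 against 0.04 ± 0.0141 (X, 156790 to 157249, adjusted p = 4.12e-09) and RPL35B at 1 ± 0 against 0.04 ± 0.0141 (IV, 217603 to 218007, adjusted p = 1.36e-08). RPL35A, RPL19B, RPL33A, RPL14A, RPL14B, RPL2B and the first RPL7A intron rose by 0.935 to 0.95. Beyond ribosomal protein genes, ACT1 rose from 0.045 ± 0.00707 to 0.84 ± 0.198 (VI, 54378 to 54686, adjusted p = 3.75e-06), the translation factor genes TEF4 and EFB1 by 0.93 and 0.9, the mRNA export factor gene YRA1 by 0.73, and QCR9, of respiratory complex III, from 0.455 ± 0.0212 to 1 ± 0. REC107 rose from 0.885 ± 0.0495 to 0.97 ± 0.0141 (adjusted p = 0.00725). The falls were BET1, a vesicle transport gene (IX, 348364 to 348494, 0.26 ± 0.0283 against 0.385 ± 0.0212, adjusted p = 0.0363), and A3SS events of RPS7A (by 0.085) and VPS75 (by 0.055).

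Of 319 events 138 rose and 3 fell in Ribo-Zero dbr1. Annotated introns took 119 of the rises, out of 205, with a median PSI of 0.945 against 0.21 (camera adjusted p = 1.37e-09, adjusted p = 0.00484 with an estimated correlation, 3.54e-10 to 0.00484 over all alternatives). The median difference of single annotated introns was smaller, 0.245, and 0.045 over the 114 of them outside ribosomal protein genes. Ribosomal protein events rose in 96 of 115 cases, with 88 of 91 annotated introns among them, and 1, an A3SS event, fell (97 and 1 adjusted over the list alone), with a median difference of 0.85 (adjusted p = 3.47e-22, adjusted p = 1.69e-07 with an estimated correlation, the highest of all alternatives). Of 87 unannotated introns 14 rose. Their median difference was 0 and their mean 0.069. With a median PSI of 0.985 in the control they could hardly rise, and their place below the other introns in camera is largely the counterpart of the annotated shift (adjusted p = 4.03e-07, adjusted p = 0.00484 with an estimated correlation, 1.93e-08 to 0.00484 over all alternatives). Among smaller lists 11 of 13 regulated, 8 of 12 snoRNA host, 3 of 9 cytoskeleton, 2 of 7 RNA processing and 1 of 3 mitochondria introns rose, none past in camera. Cytoskeleton and RNA processing lay below other introns there although their means were positive (0.219 and 0.176). All but 2 of the 15 introns named for size of change or in every comparison passed whichever library was left out (highest adjusted p 0.00761), as did TEF4, EFB1, YRA1 and QCR9 (highest 1.16e-06). BET1 failed without dbr1 replicate 2, -rap replicate 1 or -rap replicate 2 (up to 0.145), and REC107 without dbr1 replicate 2 or -rap replicate 2 (up to 0.0951). Genotype cannot be told apart here from other differences between the cultures. Excised lariats may also be counted as intron reads in these libraries, so a higher PSI here need not be retained pre-mRNA.

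**Figure D1:**
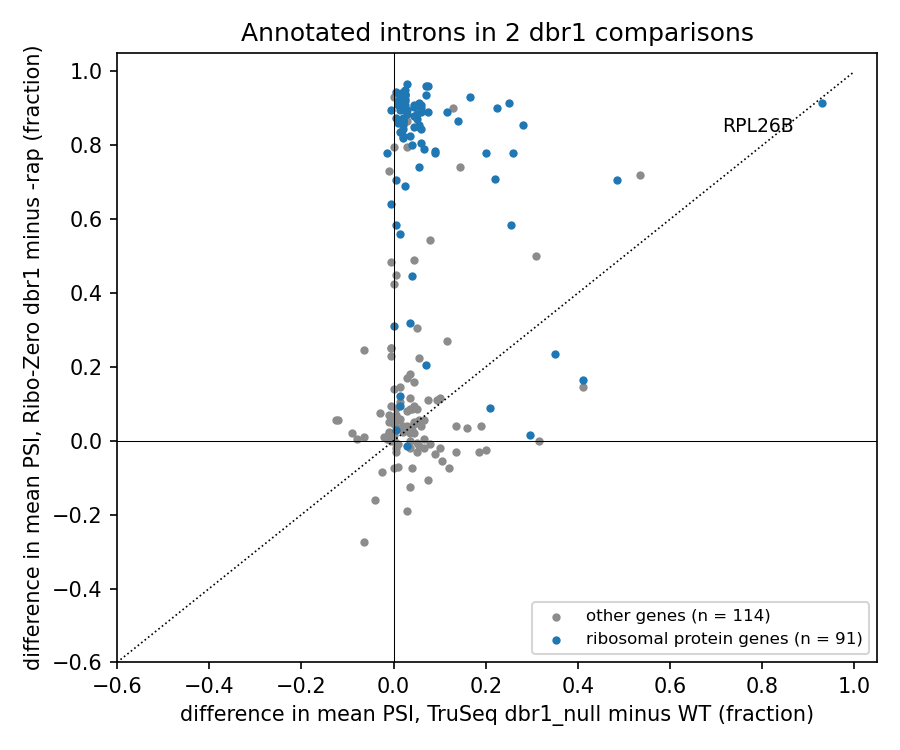
Difference in mean PSI between dbr1 and its control for each annotated intron, TruSeq on the x axis and Ribo-Zero on the y axis, with ribosomal protein introns marked. The median difference of 91 ribosomal protein introns was 0.03 in TruSeq and 0.87 in Ribo-Zero, that of 114 others 0.03 and 0.045, and 155 of the 205 introns lay above the line of equality.

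The sk1 cells, compared with the same S288c -rap libraries, differed at few introns. MRA1 was lower in sk1 (XVI, 582559 to 582701, 0.46 ± 0.0424 against 0.91 ± 0.0424, adjusted p = 0.0056). COX5B, the hypoxic isoform of a cytochrome oxidase subunit, was higher (IX, 155223 to 155310, 0.575 ± 0.0778 against 0.28 ± 0.0141, adjusted p = 0.0226). Unannotated introns antisense to CHS5 (XII, 789114 to 789218, 0.57 ± 0.141 against 0.985 ± 0.00707, adjusted p = 0.000198), in YAL064W-B (I, 12488 to 12775, 0.715 ± 0.0212 against 0.975 ± 0.00707, adjusted p = 0.000198) and in SBA1 (0.945 ± 0.00707 against 1 ± 0, adjusted p = 0.00264) were lower, and one in RSB1 was higher by 0.02 (adjusted p = 0.043). In total 2 of 294 events were higher and 4 lower (1 and 5 with an offset of 0.05, 1 and 4 with robust moderation). None of 115 ribosomal protein events passed limma's test, over all introns or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The list as a whole lay lower (median difference −0.02, camera adjusted p = 0.0123, adjusted p = 0.514 with an estimated correlation, 0.000105 to 0.514 over all alternatives). That call was lost without sk1 replicate 2 (adjusted p = 0.141) or -rap replicate 2 (adjusted p = 0.371), and when ranked by the moderated statistic (0.135). No other list passed except cytoskeleton among annotated introns alone (adjusted p = 0.0885, then 0.0223, and 0.0223 to 0.514 over all). ACT1 and REC107 were at 0.05 ± 0 and 0.83 ± 0.0707 (adjusted p = 1 and 0.716). YAL064W-B, SBA1 and the CHS5 antisense intron passed whichever library was left out (highest adjusted p 0.036). MRA1 failed without sk1 replicate 2 or -rap replicate 2 (up to 0.105), COX5B without these or -rap replicate 1 (up to 0.192) and RSB1 without any 1 of the 4 (up to 0.167). The count was 3 without -rap replicate 2.

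Growth under +rap against -rap addresses regulated splicing of ribosomal protein transcripts in S288c. RPS9A showed the largest rise (XVI, 404957 to 405457, 0.955 ± 0.00707 against 0.295 ± 0.0354, adjusted p = 0.0025). The second RPL7A intron, which hosts a snoRNA, rose from 0.28 ± 0.0283 to 0.78 ± 0.113 (VII, 365527 to 365985, adjusted p = 0.00632). RPS17B, RPS14B, RPL31B, RPS13 and RPL18B rose by 0.415 to 0.495, and unannotated introns of RPS26B and RPS29A by 0.525 and 0.385. Both RNA helicase gene DBP2 (XIV, 414912 to 415913, 0.585 ± 0.134 against 0.17 ± 0.0141, adjusted p = 0.0068) and export factor gene YRA1 (0.565 ± 0.134 against 0.24 ± 0.0424, adjusted p = 0.00659) rose. The introns of these genes are classic cases of autoregulation. In the opposite direction, PTC7, a phosphatase gene whose unspliced mRNA is also translated, fell from 0.92 ± 0.0141 to 0.56 ± 0.113 (VIII, 251156 to 251248, adjusted p = 0.0217) and QCR9 from 0.455 ± 0.0212 to 0.3 ± 0.0283 (VII, 859261 to 859473, adjusted p = 0.0136). An unannotated LIA1 intron fell by 0.07, and A3SS or A5SS events of VPS75, RPL19B, RPL7A, RPL23A and RPS0B by 0.03 or less. ACT1 did not move (0.045 ± 0.00707 in both, adjusted p = 1) and REC107 was at 0.85 ± 0.0849 against 0.885 ± 0.0495 (adjusted p = 0.702).

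Altogether 55 of 306 events rose under +rap and 10 fell, and 50 of the rises were among 194 annotated introns. Ribosomal protein events accounted for 51 rises and 6 falls out of 114 (71 and 7 adjusted over the list alone). All 6 falls were A3SS or A5SS events, whose direction is not known, and annotated introns had 47 rises among 90 and no fall. The list was shifted up (camera adjusted p = 1.74e-13, adjusted p = 0.000154 with an estimated correlation, the highest of all alternatives). Annotated introns were shifted up (adjusted p = 7.19e-05, adjusted p = 0.104 with an estimated correlation, 2.87e-06 to 0.104 over all alternatives). Regulated introns had 5 rises and 1 fall among 12, snoRNA host introns 3 and 1 among 12 (the fall an A3SS or A5SS event of RPL7A), and RNA processing introns 2 rises among 7, none past in camera. Of 3 mitochondria introns QCR9 fell (adjusted p = 0.0512 for the list, 0.017 to 0.109 over all alternatives). That list passed with an offset of 0.05 (0.0207), among annotated introns alone (0.017), without -rap replicate 1 (0.0264) and without +rap replicate 2 (0.0366). None of 8 cytoskeleton introns passed limma's test, and none had an unadjusted p under 0.05. Unannotated introns, with 4 rises and 1 fall among 86, were not past in camera (adjusted p = 0.0905, 0.00991 to 0.652 over all alternatives), but were without +rap replicate 1 (0.00991) and with an offset of 0.05 (0.0432). Most of these calls rested on single libraries: the count was 1 without +rap replicate 2, 5 without -rap replicate 1 and 11 without -rap replicate 2, and of the 20 introns named for size of change or in every comparison RPS9A alone passed whichever was left out (highest adjusted p 0.0364; up to 0.284 for the others). YRA1 failed without -rap replicate 1 or +rap replicate 2 (up to 0.0734).

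Meiotic development was followed in SK1 cells through 12 h in sporulation medium, each time set against the same 0 h libraries. At 3 h the intron of SPO1 was spliced far more, with PSI falling from 0.925 ± 0.00707 to 0.385 ± 0.00707 (XIV, 609791 to 609874, adjusted p = 3.74e-05). REC107, a recombination gene spliced with the help of the meiotic factor Mer1, fell from 0.915 ± 0.00707 to 0.72 ± 0.0141 (X, 469184 to 469263, adjusted p = 0.0279). Ribosomal protein introns fell too: the first RPL7B intron from 0.99 ± 0 to 0.405 ± 0.12 (XVI, 173163 to 173571, adjusted p = 0.01), an unannotated 5′ intron of RPS22B from 0.865 ± 0.163 to 0.225 ± 0.0919 (XII, 855878 to 856427, adjusted p = 0.0374), and RPL33B, RPS14B, RPL16B, RPL22B and RPS11B by 0.255 to 0.45. An unannotated intron of FMP45, a gene for an eisosome protein, fell from 0.93 ± 0.0141 to 0.415 ± 0.0919 (IV, 60479 to 61787, adjusted p = 0.01) and MPT5, for a Puf family RNA binding protein, by 0.37. Rises were APE2, an aminopeptidase gene (XI, 155272 to 155654, 0.755 ± 0.12 against 0.55 ± 0.0424, adjusted p = 0.0432), and unannotated introns in ECM9, MLO50 and ESP1, by 0.05 or less. In all 4 of 287 events rose and 24 fell (5 and 15 with PSI untransformed). The ACT1 intron was at 0.05 ± 0 against 0.075 ± 0.0212 (adjusted p = 0.709).

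Of 111 ribosomal protein events none rose and 15 fell at 3 h (20 fell adjusted over the list alone). The list was shifted down (camera adjusted p = 7.6e-13, adjusted p = 0.000203 with an estimated correlation, at most 0.00837 over all alternatives). Both measured Meiotic introns fell, as did 5 of 13 regulated introns, among them RPL28 (0.155 ± 0.0636 against 0.39 ± 0.0707, adjusted p = 0.0136), DBP2 (0.13 ± 0.0849 against 0.34 ± 0.0141, adjusted p = 0.0432) and YRA1 (0.16 ± 0.0283 against 0.33 ± 0, adjusted p = 0.0433). Annotated introns, with 1 rise and 21 falls among 181, were shifted down (adjusted p = 0.000122, adjusted p = 0.0752 with an estimated correlation, 3.86e-09 to 0.881 over all alternatives, the highest without 3 h replicate 1). Unannotated introns, with 3 rises and 3 falls among 80 and a median difference of 0 and mean of −0.00613, lay above the rest (adjusted p = 0.000129, adjusted p = 0.0548 with an estimated correlation, 3.34e-06 to 0.524 over all alternatives, the highest without 3 h replicate 1). Cytoskeleton (7), RNA processing (7, with 2 falls), snoRNA host (11, with 2 falls), mitochondria (3) and regulated introns were not past in camera. The count was 14 and 8 without 0 h replicates 1 and 2, and 15 and 81 without 3 h replicates 1 and 2. SPO1, FMP45 and RPL7B passed whichever was left out (highest adjusted p 0.0486), and the other 12 of 15 introns named for size of change or in every comparison failed without 1 or more of these 4 libraries (up to 0.341). RPL28, DBP2 and YRA1 each failed without 2 or more of them (up to 0.247).

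At 6 h SPO1 (0.365 ± 0.0778, adjusted p = 2.96e-05), FMP45 (0.39 ± 0, adjusted p = 0.00626) and REC107 (0.745 ± 0.0495, adjusted p = 0.034) were again below 0 h. RPL7B, RPL33B, RPL16B, RPS14B, RPS11B, RPS13, MPT5 and the second RPL7A intron fell by 0.225 to 0.475. Rises appeared at an unannotated intron of SIP18, a desiccation tolerance gene (XIII, 610808 to 611036, 0.81 ± 0.0566 against 0.385 ± 0.0778, adjusted p = 0.0029), at RUB1, a ubiquitin-like modifier gene (0.56 ± 0.0707 against 0.27 ± 0, adjusted p = 0.0241), at BET1 (0.545 ± 0.00707 against 0.32 ± 0.0424, adjusted p = 0.0164) and at unannotated introns of OSH2 and IDP3, by 0.285 and 0.16, and of ECM9, MLO50 and ESP1, by 0.06 or less. Counts were 8 rises and 23 falls of 299 events (11 and 17 with PSI untransformed). Ribosomal protein events fell in 14 of 112 cases with no rise (16 fell adjusted over the list alone). Their shift had camera adjusted p = 3.39e-09 (adjusted p = 0.00397 with an estimated correlation, the highest of all alternatives). Annotated introns (2 rises, 18 falls of 188) lay lower and unannotated introns (6 rises, 5 falls of 84, median difference 0) higher than the rest, each with adjusted p = 0.00482. Both calls were lost with an estimated correlation (adjusted p = 0.267 and 0.218, the highest of the alternatives, whose lowest were 0.000526 and 0.00064) and without 0 h replicate 2 (0.0812 and 0.0682). No other list tested passed. The count was 17 and 9 without 0 h replicates 1 and 2, and 13 and 10 without 6 h replicates 1 and 2. SIP18, FMP45, SPO1 and MLO50 passed throughout (highest adjusted p 0.0395), and the other 15 of 19 named introns failed without 2 or more of these libraries (up to 0.223).

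The 7.5 and 8.5 h libraries held values for fewer introns (210 and 176 tested), and their changes ran in both directions. SPO1 remained low (0.335 ± 0.0212 and 0.315 ± 0.00707, adjusted p = 6.96e-06 and 4.43e-06), and REC107 reached 0.75 ± 0.0141 and then 0.605 ± 0.0495 (adjusted p = 0.0148 and 0.00084). RPL34A rose to 0.58 ± 0.141 and then 0.89 ± 0.0424 from 0.23 ± 0.0141 (V, 269752 to 270148, adjusted p = 0.0259 and 0.000234). APE2 rose to 0.99 ± 0 and 0.905 ± 0.0354 (adjusted p = 1.6e-06 and 0.000129). At 8.5 h CQD1, a mitochondrial coenzyme Q distribution gene, rose from 0.15 ± 0.0283 to 0.7 ± 0.099 (XVI, 345445 to 345596, adjusted p = 0.000115), DBP2 from 0.34 ± 0.0141 to 0.84 ± 0.0707 (adjusted p = 0.000357), and YJR079W fell from 0.995 ± 0.00707 to 0.58 ± 0.0141 (X, 580348 to 581052, adjusted p = 1.84e-07). GCR1, a transcriptional activator of glycolytic genes, fell at an unannotated intron from 0.955 ± 0.0212 to 0.555 ± 0.12 and 0.66 ± 0.0707 (XVI, 412257 to 412995, adjusted p = 7.39e-05 and 0.000147), and RPL28 from 0.39 ± 0.0707 to 0.07 ± 0.0141 and 0.145 ± 0.0354 (adjusted p = 9.26e-05 and 0.00145). RPL33B, FMP45, BUD25 and a VMA9 A3SS event (III, 107034 to 107304, 0.395 ± 0.0212 and 0.41 ± 0.0141 against 0.735 ± 0.00707) also fell at both times. At 7.5 h OSH2, GIM4, ARF2, RUB1 and HAC1 rose by 0.23 to 0.47, and YNL194C, RPS14B and MPT5 fell by 0.31 to 0.34. At 8.5 h RPL34B, ARF2, SIP18, RPS13 and YEL076C-A rose by 0.265 to 0.385, and LSM2 and RPS9A fell by 0.295 and 0.265. An event in the rDNA was also higher at both times (1 ± 0 against 0.625 ± 0.233). Its span of 9138 nt matches the repeat distance within 1 nt. Reads joining neighbouring repeat copies would give that span, so it need not be an intron, here or at 12 h and in the F-test below.

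At 7.5 h 24 events rose and 43 fell, and at 8.5 h 30 rose and 42 fell. Ribosomal protein events had 2 rises and 20 falls of 70, the same counts adjusted over the list alone, and then 4 rises and 16 falls of 34 (5 and 16 adjusted over the list alone). Of these falls 9 and 7 were A3SS events. At 7.5 h the list was shifted down with camera adjusted p = 0.00179 (adjusted p = 0.205 with an estimated correlation, 0.000356 to 0.205 over all alternatives, and 0.179 among annotated introns alone). At 8.5 h this was adjusted p = 0.0136 (adjusted p = 0.262 with an estimated correlation, 0.014 to 0.613 over all alternatives, the highest among annotated introns alone, and 0.0838 without 8.5 h replicate 1). Regulated introns fell in 6 of 10 cases at 7.5 h (adjusted p = 0.0317, adjusted p = 0.33 with an estimated correlation, 0.0169 to 0.33 over all alternatives, 0.0555 without 0 h replicate 1 and 0.321 without 7.5 h replicate 2). At 8.5 h 6 of 10 fell and 1 rose (adjusted p = 0.0575). Of alternative 3′ splice site events 10 of 16 and 9 of 14 fell and 1 rose each time, with median differences of only −0.02 and −0.025. Other lists with at least 3 measured introns were not past in camera. Of 2 measured mitochondria introns, too few to test, QCR9 rose (0.27 ± 0.0141 and 0.305 ± 0.00707 against 0.195 ± 0.00707, adjusted p = 0.0247 and 0.00223) and COX5B fell at 8.5 h (0.13 ± 0.0141 against 0.27 ± 0.0849, adjusted p = 0.014). ACT1 was at 0.065 ± 0.00707 and 0.07 ± 0.0141. Of introns named for size of change or in every comparison 12 of 21 and 15 of 20 passed whichever library was left out (highest adjusted p 0.0352 and 0.0463). The rest failed without 1 or more of the 0 h, 7.5 h and 8.5 h libraries (up to 0.231 and 0.161), and without 0 h replicate 2 the 7.5 h count was 44.

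By 12 h retention had risen at many annotated introns. HNT1, a nucleotide hydrolase gene, stood at 0.69 ± 0.0283 against 0.13 ± 0.0283 (IV, 239399 to 239509, adjusted p = 6.58e-06). BOS1 and BET1, both SNAREs of transport from endoplasmic reticulum to Golgi, rose from 0.25 ± 0.0707 to 0.79 ± 0.156 (XII, 286468 to 286556, adjusted p = 0.00705) and from 0.32 ± 0.0424 to 0.775 ± 0.0495 (adjusted p = 0.000138). Actin-bundling gene SAC6 rose from 0.15 ± 0.0141 to 0.54 ± 0.127 (adjusted p = 0.00134), the tubulin gene TUB3 by 0.35 (adjusted p = 0.00728) and the profilin gene PFY1 by 0.175 (adjusted p = 0.0106), so that 4 of 6 cytoskeleton introns rose. RPS21A, RPL17A, RPL2A, RPS7B and RUB1 rose by 0.36 to 0.43, and the rDNA event stood at 1 ± 0. Falls were at the first RPL7B intron (0.635 ± 0.403 against 0.99 ± 0, adjusted p = 0.00989), RPS9A (0.67 ± 0.113 against 0.94 ± 0.0141, adjusted p = 0.0171), the annotated RPS22B intron (XII, 856575 to 857057, 0.805 ± 0.106 against 1 ± 0, adjusted p = 0.00303), a VMA9 A3SS event by 0.225, and RPL28, YRA1, RPS16A, RPS16B, EFB1 and an ECM33 A3SS event by 0.16 or less. SPO1 was back at 0.905 ± 0.0212 (adjusted p = 0.44) and REC107 at 0.81 ± 0.0141 (adjusted p = 0.0678).

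In total 51 of 267 events rose at 12 h and 21 fell (54 and 9 with PSI untransformed). Annotated introns had 41 rises and 8 falls among 170 (45 and 8 adjusted over the list alone), with a median PSI of 0.388 against 0.285 (camera adjusted p = 0.0181, adjusted p = 0.297 with an estimated correlation, 0.00041 to 0.297 over all alternatives, and 0.165 without 0 h replicate 1). The median difference of single annotated introns was 0.05. Ribosomal protein events, with 7 rises and 13 falls among 95, 5 of the falls A3SS events (5 and 12 adjusted over the list alone), lay lower relative to other introns, with a median difference of −0.01 but a mean of 0.0249 (adjusted p = 0.0181, adjusted p = 0.297 with an estimated correlation, 0.00177 to 0.297 over all alternatives, and 0.135 without 0 h replicate 2). Regulated introns fell in 3 of 9 cases (adjusted p = 0.0181, adjusted p = 0.297 with an estimated correlation, 0.00484 to 0.297 over all alternatives, and 0.0683 and 0.113 without 0 h replicates 1 and 2). Cytoskeleton introns were not past in camera (adjusted p = 0.14, 0.0329 to 0.344 over all alternatives, the lowest without 12 h replicate 2). Nor were snoRNA host introns (11, with 3 falls), RNA processing (7, with NCB2 rising to 0.96 ± 0.0141 from 0.675 ± 0.191) or mitochondria (3, of which QCR9 and QCR10 rose). The count was 39 without 0 h replicate 2 and 40 without 12 h replicate 1. HNT1, BET1, SAC6, RPL17A, RUB1, RPS16B, RPS22B and the rDNA event passed throughout (highest adjusted p 0.0271), and the other 12 of 20 named introns failed without 1 or more of the 0 h and 12 h libraries (up to 0.272).

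Over all 6 times limma's F-test passed for 89 of 159 events, 48 of 77 annotated introns, 31 of 67 unannotated introns and 27 of 34 ribosomal protein events. The smallest p belonged to YJR079W (adjusted p = 1.05e-06), HNT1 (2.98e-06) and SPO1 (3.14e-06), followed by APE2, its A3SS event, the rDNA event, VMA9, RSB1, MLO50 and DBP2 (0.000199). These 10 passed whichever of the 12 libraries was left out (highest adjusted p 0.00188). REC107 passed as well (adjusted p = 0.00768), and the other Meiotic introns lacked values at some times.

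**Figure D2:**
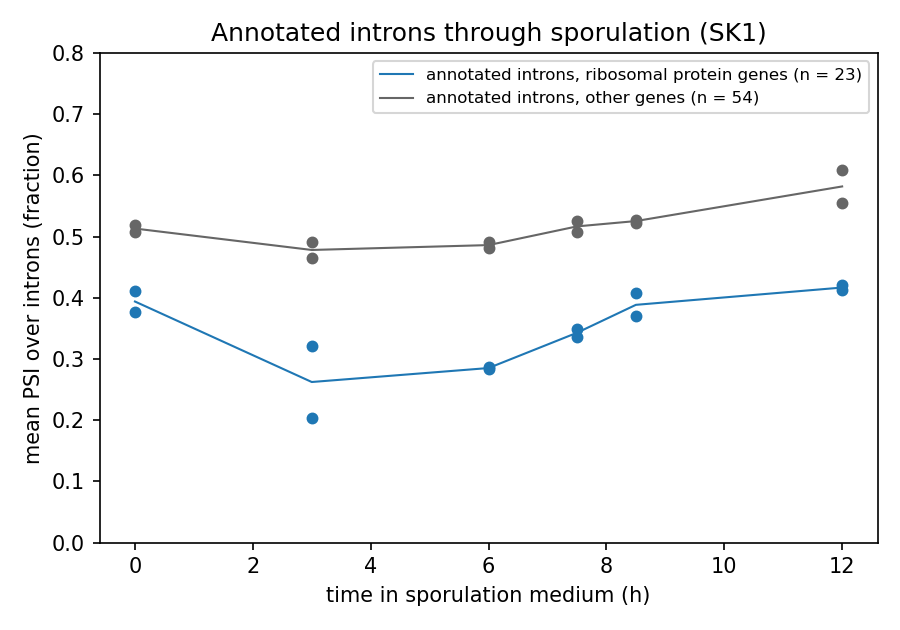
Mean PSI against hours in sporulation medium, each point a library, over annotated introns with a value in all 12 libraries. Ribosomal protein introns (23) were at 0.394 ± 0.0234 at 0 h, 0.262 ± 0.0827 at 3 h and 0.417 ± 0.00523 at 12 h, and the 54 others at 0.513, 0.478 and 0.582.

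Branch-seq located branch points by sequencing opened lariats, which asks where the branch nucleotide lies in each intron. Among annotated sites, in 192 genes, the actin-severing gene COF1 (XII, 40353 on sacCer2, 2850 CPM) and the ubiquitin-conjugating enzyme gene UBC4 (II, 407047, 2316 CPM) led, ahead of VMA10 (1390), YDL012C (1295), YIP3 (1187), RPO26 (1048), ARP9 (836), LSB3 (787), PMI40 (674) and QCR10 (674). The unannotated sites, of which 153 were assigned to a gene, were led by RBS1 (IV, 122159, 465 CPM) and the cell cycle gene BCK2 (V, 517901, 395 CPM), then MRM2 (95.2), PUS2 (94.5), USV1 (65.8) and PRO3 (46.4). Sites assigned to no gene stood among these at XIII, 559830 (129 CPM), XII, 982469 (71.8 CPM) and VII, 436364 (39.9 CPM). The median was 113 CPM at annotated (quartiles 1.03 and 276) and 0.626 CPM at unannotated sites (0.167 and 2.10). The difference in median log2(CPM + 1) was 6.13 across sites (permutation p = 1e-05, the smallest the resamples can give). At least 10 CPM was reached by 129 annotated (65.2%, 58.1 to 71.8) and 24 unannotated sites (8.96%, 5.82 to 13.0), and unannotated sites held 4.83% of all listed CPM, 70.4% of it in the top 10. With a single experiment there is no replicate error, and sites are not independent replicates.

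Ribosomal protein genes had far lower Branch-seq signal than other annotated genes, a comparison made after low values at these sites had been noticed, with a median of 0.459 CPM over 47 sites against 173 CPM over 151 (difference in median log2(CPM + 1) −6.90, permutation p = 1e-05). Their introns were also longer, with a median of 407 against 93.0 nt. Across 185 genes CPM fell with intron length (Spearman rho = −0.610, permutation p = 1e-05, adjusted p = 4e-05; Pearson r = −0.699, permutation p = 1e-05, adjusted p = 2e-05). There were 4 relations in the family, and without the 2 genes farthest in length rho and r were −0.606 and −0.698. Within ribosomal protein genes no relation was seen (rho = 0.0226, permutation p = 0.880; r = 0.0784, p = 0.600; 46 genes), while within other genes it held (rho = −0.318, permutation p = 0.00019, adjusted p = 0.00038; r = −0.461; 139 genes). These relations are across genes, which are not independent replicates.

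**Figure D3:**
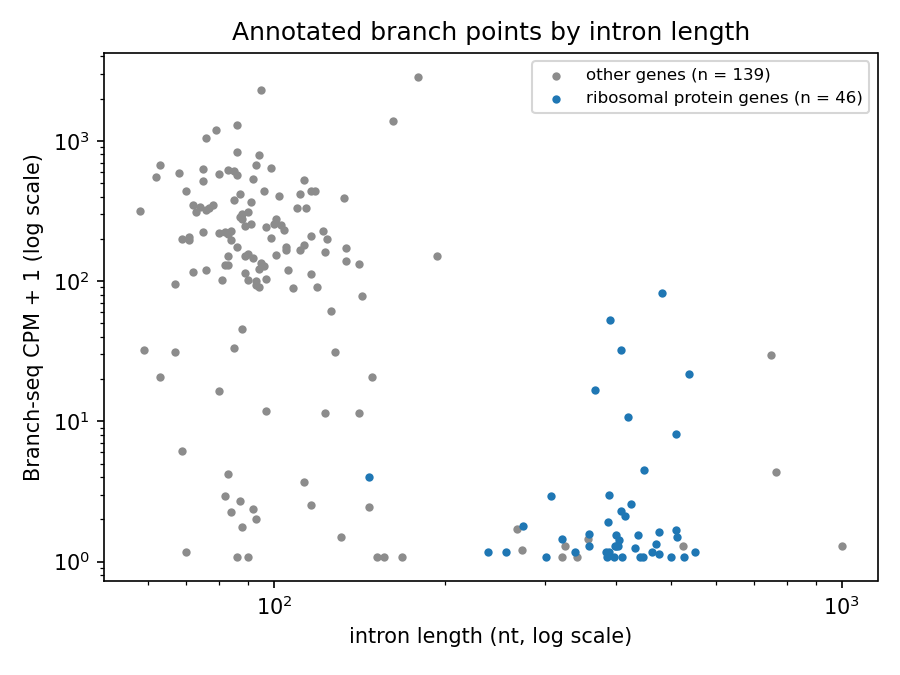
Branch-seq CPM of annotated sites against intron length, ribosomal protein genes marked. The 46 ribosomal protein genes had a median intron of 407 nt and the 139 others one of 93.0 nt, with rho = −0.610 over all 185.

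Lariat-seq, which reads across the branch junction, gave 3541 junction reads at 58 sites, a median of 11.5 per site. The U3 snoRNA gene SNR17A (XV, 780121 to 780266) took 735 reads (20.8%, 19.4 to 22.1) and YOP1, a membrane-shaping gene of the endoplasmic reticulum, 550 (15.5%). HNT1 (366), the mitochondrial ribosome gene MRPL44 (313), SEC14 (267), RPP1B (139), MRA1 (125), SAC6 (110), ARP2 (108) and PFY1 (90) followed, and the top 10 held 2803 reads (79.2%). Sites with both ends annotated numbered 40 (69.0%, 55.5 to 80.5) and took 3399 reads (96.0%, 95.3 to 96.6). Sites with neither end annotated numbered 14, with 105 reads (2.97%, 2.43 to 3.58), 3 sites joined an annotated 5′ splice site to an unannotated branch point (32 reads), and 1, in RPL2B, the reverse (5 reads). The distance from 5′ splice site to branch point had a median of 111 nt. This is a single library, and 49 sites had at least 3 reads.

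Matched by gene, 34 of 58 Lariat-seq sites fell in a gene with a Branch-seq site (58.6%, 44.9 to 71.4), 31 in the annotated and 11 in the unannotated list. Sites in no gene or antisense to one could not be matched but count in the 58, which lowers this share. Branch-seq sites assigned to no gene could not be matched either. Of 17 unannotated Lariat-seq branch points, 8 were assigned to a gene and could be matched. Of these 8, 4 lay in genes of the unannotated Branch-seq list. They were the bromodomain gene BDF2 (23 reads, 31.9 CPM), RBS1 (19 reads, 465 CPM), the phospholipid synthesis gene CPT1 (11 reads, 16.6 CPM) and TAF11, for a TFIID subunit (4 reads, 0.501 CPM). RBS1 was the only gene with unannotated features in Branch-seq, Lariat-seq and the PSI table, where it had 3 events. Lariat-seq reads did not track Branch-seq CPM across 30 shared genes (rho = −0.129, permutation p = 0.492, adjusted p = 0.656; r = −0.127, permutation p = 0.498, adjusted p = 0.600; rho = −0.0592 without the 2 farthest; genes are not independent replicates). The builds of the assays differ, so a shared gene does not show that the branch nucleotide was the same.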

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

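Chosen after the results had been seen were the difference in dbr1 effect between preparations, 12 h against 3 h, and the tests weighing explanations, which draw in part on the planned comparisons of dbr1 and sk1 with -rap.

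The dbr1 effect differed between the preparations, by a test of the difference itself over all libraries: 120 of 319 events differed, 117 with a larger and 3 with a smaller change in Ribo-Zero than in TruSeq (107 to 127 events over the alternatives run). Over 205 annotated introns the median difference in PSI was 0.245 in Ribo-Zero and 0.03 in TruSeq. This same difference, rather than a separate test, argues against retained pre-mRNA of like size in both preparations. Over 91 annotated ribosomal protein introns, a list fixed beforehand, the medians were 0.87 in Ribo-Zero and 0.03 in TruSeq. The 119 annotated introns that rose in Ribo-Zero, by a median of 0.85, had a 90th percentile of 0.212 in TruSeq, but were picked for that rise. A control unlike every other culture is argued against for annotated introns as a set. Their median PSI was 0.22 and 0.225 in the -rap libraries, 0.19 and 0.23 in sk1, and 0.895 and 0.91 in dbr1. Of 91 annotated ribosomal protein introns, 88 rose in dbr1 and 0 passed in sk1 against the same -rap libraries. Counts of calls leave it open for single introns: sk1 differed from -rap at 6 events where dbr1 differed at 141. These were 10 against 52 among introns present in every library and 19 against 135 with only the groups compared. Excised lariats, which persist without Dbr1 and which poly(A) selection would remove, may be counted as intron reads in Ribo-Zero. This stays open. The relation of dbr1 PSI to control PSI cannot decide it, because lariat reads added to the control's intron signal could also leave rho positive. PSI in dbr1 rose with PSI in the control within ribosomal protein introns (rho = 0.290, permutation p = 0.00565) and within others (rho = 0.627, permutation p = 1e-05, the smallest the resamples can give). The pooled rho of −0.037 over 205 introns (permutation p = 0.600) mixes these classes, and many dbr1 values sit at the ceiling of PSI. Within Ribo-Zero genotype and culture are confounded, and preparation cannot be told apart from the cultures used for each.

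The change in sporulation medium differed between 12 h and 3 h at 121 of 283 events, 107 higher and 14 lower at 12 h (60 without 3 h replicate 1, 64 without 12 h replicate 1). Most of the Meiotic introns named here could not be tested against 0 h for want of values, and 5 of 9 measured rose: SPO22 (IX, 225810 to 225899, from 0.345 ± 0.0212 to 0.96 ± 0.0141, adjusted p = 0.000153), MND1 (VII, 157200 to 157282, from 0.435 ± 0.0495 to 0.955 ± 0.00707, adjusted p = 0.000538), REC114 (XIII, 537449 to 537564, from 0.24 ± 0.0141 to 0.76 ± 0.0141, adjusted p = 0.000834), SPO1 and HFM1. Of Mer1 targets SPO22 and HFM1 rose (2 of 5 introns), while AMA1 (0.21 ± 0.0283 against 0.295 ± 0.0354, adjusted p = 0.174) and REC107 (0.81 ± 0.0141 against 0.72 ± 0.0141, adjusted p = 0.258) did not pass. As a list Meiotic introns were not past in camera (adjusted p = 0.286), nor were ribosomal protein events (43 rises and 6 falls of 93, with 3 of the falls A3SS events, adjusted p = 0.458). Annotated introns were (95 rises and 2 falls of 186, adjusted p = 1.05e-11, adjusted p = 0.00113 with an estimated correlation), and unannotated introns, near the ceiling of PSI, lay below the rest (12 rises and 7 falls of 74, adjusted p = 3.56e-05, adjusted p = 0.0247 with an estimated correlation). GMC2, a gene for a synaptonemal complex protein, was chosen after its values were seen (XII, 1024573 to 1024654, from 0.12 ± 0 to 0.93 ± 0.0141, adjusted p = 3.1e-05).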

How the results depend on the processing

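Alternatives added after seeing the data were values spread within their rounding, rDNA events left out, the 7.5 and 8.5 h libraries left out, lists among annotated introns alone, lists ranked by the moderated statistic, all alternatives of 12 h against 3 h and of the difference in dbr1 effect, those of the Branch-seq relations to length and gene class, and those of the overlap of +rap and 3 h introns. Not run were leaving out each gel fraction, scaling each fraction to one total and fraction against lariat length (the fractions are pooled), the branch motif with its settings (sequence was not used here), and overlap of positions exactly, within 2 or within 5 nt (the builds differ). Of 170 calls of named introns, with 2457 values under alternatives, 2007 stayed past the threshold in the same direction, 450 did not pass, 0 reversed, and 122 calls had at least 1 alternative that did not pass. Of 18 named introns not called, 3 passed under an alternative. Where leaving out a library leaves a group with 1, that library is assumed to vary like the other groups. The cause was not tested for any of the changes below, except where fewer introns were tested or a stricter threshold was set. The depth behind PSI is unknown, and thin 7.5 and 8.5 h libraries limit which introns can be compared at all.

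Counts of changed events moved by more than 1.5 times as follows. For TruSeq dbr1_null the 10 became 5 with PSI untransformed, 2 with mean PSI between 0.02 and 0.98, 3 at a difference of at least 0.1, a median of 2 with values spread within their rounding, and 10 to 26 leaving out a library. For upf1_null the 49 became 32 untransformed, 29 with mean PSI between 0.02 and 0.98, 21 with only the groups compared, 30 with robust moderation, 20 at a difference of at least 0.1, 9.5 with values spread within their rounding, and 16 to 23 leaving out a library. For +rap the 65 became 19 among introns present in every library (fewer tested), 11 with only the groups compared, and 1 to 62 leaving out a library. At 3 h the 28 became 18 with offset 0.001, 1 with only the groups compared, and 8 to 81 leaving out a library. At 6 h the 31 became 18 among introns present in every library, 17 with only the groups compared, and 9 to 17 leaving out a library. At 7.5 h the 67 became 19 with only the groups compared, 31 at a difference of at least 0.1, and 44 to 68 leaving out a library. At 8.5 h the 72 became 33 with only the groups compared and 42 at a difference of at least 0.1. At 12 h the 72 became 32 with only the groups compared, 46 at a difference of at least 0.1, and 39 to 63 leaving out a library. For Ribo-Zero dbr1 the 141 became 52 among introns present in every library. For sk1 the 6 became 10 with offset 0.001, 10 among introns present in every library, 19 with only the groups compared, and 3 to 8 leaving out a library. The F-test count of 89 became 54 at a difference of at least 0.1. For 12 h against 3 h the 121 became 79 untransformed, and 60 to 137 leaving out a library. Without the 7.5 and 8.5 h libraries the counts were 30 at 3 h, 45 at 6 h, 74 at 12 h and 111 of 251 in the F-test. Leaving out rDNA events moved none of these counts by 1.5 times.

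Replicate numbers were also used as a block. The labels do not pair libraries by number, and replicate differences of the groups compared correlated from −0.383 to 0.362 over 10 comparisons (0.311 for dbr1_null, −0.0979 for upf1_null). With the block the count was 2 for dbr1_null and 11 for upf1_null, and in dbr1_null the shifts of cytoskeleton (0.213) and RNA processing (0.000686) turned upward.

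Lists past the threshold (24 of 80 tests) changed in number. Among annotated introns alone, where annotated and unannotated introns are no lists, there was 1 in dbr1_null, 1 in upf1_null, 1 at 3 h, 1 at 6 h, 0 at 7.5 h, 0 at 8.5 h, 1 in Ribo-Zero dbr1 and 2 in sk1. With an estimated correlation there was 1 under +rap, 1 at 3 h, 1 at 6 h and 0 at 7.5 h, 8.5 h, 12 h and in sk1. With offset 0.05 there were 4 under +rap, and ranked by the moderated statistic 0 at 8.5 h and 0 in sk1. Leaving out a library gave 1 to 4 at 3 h (1 without 3 h replicate 1), 1 to 4 at 6 h (1 without 0 h replicate 2), 1 to 2 at 7.5 h (1 without 0 h replicate 1 or 7.5 h replicate 2), 0 to 1 at 8.5 h (0 without 8.5 h replicate 1), 1 to 4 at 12 h (1 without either 0 h replicate) and 0 to 1 in sk1 (0 without sk1 replicate 2 or -rap replicate 2).

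A different question, whether a list moved at all, was put to fry on introns with no missing value, adjusted over the lists of each comparison. Of 74 tests 31 passed, 17 of them past in camera as well and in the same direction, 14 in fry alone, and 7 in camera alone. For 3 of the 14 camera pointed the other way: RNA processing in dbr1_null (fry up, adjusted p = 0.00124), and in Ribo-Zero dbr1 cytoskeleton (up, adjusted p = 6.15e-07) and RNA processing (up, adjusted p = 1.34e-05), none of them past in camera. In Ribo-Zero dbr1 fry used 4 cytoskeleton and 5 RNA processing introns where camera used 9 and 7, so the introns differ as well as the question. Cytoskeleton at 12 h passed in fry alone (up, 4 introns, adjusted p = 0.00395).

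No list that passed and no called intron reversed. Reversals were among 21 lists that had not passed (42 values), in mean score relative to other introns. In dbr1_null mitochondria turned to −0.200 among annotated introns and −0.602 ranked by the moderated statistic; in upf1_null cytoskeleton turned to −0.151 and −0.0659 under the same. Among annotated introns snoRNA host turned to 0.0331 at 3 h, RNA processing to −0.0518 at 6 h (−0.102 with offset 0.05) and mitochondria to −0.122 in Ribo-Zero dbr1. Mitochondria in sk1 turned to −0.00897 with offset 0.05. Leaving out a library, ranges across 0 were, in dbr1_null, −0.411 to 0.122 (cytoskeleton), −0.445 to 0.722 (Meiotic), −0.307 to 0.752 (mitochondria) and −0.353 to 0.00702 (regulated), and in upf1_null −0.152 to 0.328 (cytoskeleton) and −0.38 to 0.166 (regulated). At 3 h they were −0.431 to 0.196 (RNA processing) and −0.861 to 0.173 (snoRNA host), at 6 h −0.202 to 0.213 (RNA processing) and −0.0924 to 0.243 (mitochondria), at 7.5 h −0.234 to 0.195 (annotated), and at 8.5 h −0.00769 to 0.426 (annotated) and −0.531 to 0.863 (snoRNA host). In Ribo-Zero dbr1 the range was −0.561 to 0.169 (cytoskeleton), and in sk1 −0.438 to 0.00299 (annotated), −0.372 to 0.694 (mitochondria), −0.0499 to 0.264 (unannotated), −0.233 to 0.0811 (regulated) and −0.0961 to 0.237 (snoRNA host). Of uncalled introns, in log2 odds, ACT1 ranged over −0.17 to 0.60 in upf1_null, −0.35 to 0.21 at 6 h, −0.46 to 0.10 at 7.5 h and −0.36 to 0.20 at 8.5 h, REC107 over −1.04 to 0.30 under +rap, and the first SUS1 intron over −1.21 to 1.81 in dbr1_null (−0.015 in PSI untransformed).

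Without SNR17A, the intron with the most reads, sites with both ends annotated held 94.9% of Lariat-seq reads, and with at least 5 reads rho of Lariat-seq reads with Branch-seq CPM turned from −0.129 to 0.0362, neither past the threshold. The overlap by gene at 3 reads (61.2%) and the difference between annotated and unannotated Branch-seq sites with pseudocount 0.1 (7.28) or at least 10 CPM (2.72, a filter on the value compared) kept their direction.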

Other observations

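The overlap, the rDNA spans, the tests weighing RPL26B and the Branch-seq tests were chosen after the data had been seen, while the adjusted p values of RPL26A and RPL26B come from planned comparisons. The tests of Branch-seq signal against intron length and gene class were prompted by low CPM noticed at ribosomal protein sites in the table, before either was computed.

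Introns that rose under +rap and introns that fell after 3 h in sporulation medium overlapped. The groups compared share no library, but both tests took each intron's variance from the same fit over all 20 Ribo-Zero libraries. An intron with little spread is easier to call in both. The lists are thus not independent, and the Fisher tests below describe the overlap only. Of 270 events tested in both, 54 rose under +rap and 22 fell at 3 h, and 13 did both where 4.4 would be shared by independent lists (Fisher's exact p = 2.64e-05). Among 168 annotated introns alone it was 13 against 5.65 (Fisher's exact p = 0.000248). Among them were the ribosomal protein genes RPS13, RPL19A, RPS14B, RPS7A, RPS11B, RPL16B, RPS17A, RPL28, RPL37B and RPL33B together with YRA1 and DBP2. Most were ribosomal protein events, and within these the overlap was 11 of 111 against 6.76 (Fisher's exact p = 0.0249). It rests on single libraries: 0 were shared without +rap replicate 2 or without -rap replicate 1, and 1 without 0 h replicate 2 or without 3 h replicate 1, while 40 were shared without 3 h replicate 2. Whether the overlap would recur is therefore open, and whether introns with more reads were easier to call in both comparisons was not tested.

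The 8 rDNA events each span 9138 nt against a distance of 9137 nt between annotated repeat starts, a departure of 1 nt, and their median PSI was 1. Reads that join neighbouring repeat copies would give this span, so a change in their PSI does not show intron retention.

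The RPL26B intron changed far more than other introns in TruSeq dbr1_null. This same difference, rather than a separate test, argues against lariats carried into the TruSeq libraries to a like extent for all introns. RPL26B was picked for its large rise, so the values below restate that choice. The other 118 introns that rose in Ribo-Zero dbr1 had a 90th percentile of 0.203 (highest 0.535) in TruSeq, while the lowest difference between RPL26B replicates was 0.92. Carry-over of the RPL26B lariat alone could not be tested this way and stays open. Shared reads that raise both RPL26B and its paralog RPL26A are argued against, because RPL26A differed by 0.02 (0.1 and 0.08 against 0.08 and 0.06, adjusted p = 0.425). Shared reads that change RPL26B alone could not be tested this way and stay open. A variant at RPL26B in the deletion strain may account for it and stays open. RPL26B differed by 0.915 in the Ribo-Zero dbr1 libraries also (1 and 1 against 0.07 and 0.1, adjusted p = 1.51e-08), where many introns rose, and its mean in upf1_null was 0.095.

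Lower recovery of sites in long introns might account for the low Branch-seq signal of ribosomal protein genes (−6.90 in median log2(CPM + 1) against other sites), and stays open. The pooled relation of CPM to length (rho = −0.610 across 185 genes) takes in these genes, which have both long introns and low CPM. How much of it they account for was not computed. Within other genes CPM fell with length (rho = −0.318), but within ribosomal protein genes no relation was seen (rho = 0.0226, permutation p = 0.880), so length and other features of these genes cannot be separated here.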
